A study of Solanum lycopersicum with 6 samples.

How the data were processed

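Leaf RNA was extracted with Trizol and made into stranded mRNA libraries with a TruSeq kit, per the labels' protocols, from 3 STV-infected and 3 STV-free plants of cultivar M82. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cuffnorm 2.2.1. The genome build, annotation and settings are not given in the sources used here, so no coordinates are printed. The groups and replicate numbers come from the sample titles, and the columns were matched to samples by the sample numbers in the descriptions. The design text gives 3 plants per group and the labels do not say whether plants of the same number were grown or sampled together, so p-values measure the spread between these 6 samples.

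The deposited table gives 3 values per gene and library. The authors' FPKM columns hold fragments per kilobase scaled to library depth, per the file headers. The deposited processed signal is, as the values show, log2 FPKM minus the gene's mean log2 FPKM, with a largest difference of 0.000631 over 10061 genes above 5 FPKM in all libraries, and it was used for that check alone. The deposited count columns were treated as a score, not as raw counts: they are whole numbers, but the values skip or double whole numbers at regular spacing, as reads divided by a size factor and rounded would. The normalized count that 1 read is worth was estimated from this spacing as 0.965, 1.096, 0.822, 0.924, 1.018 and 1.177 in STV-infected replicates 1, 2 and 3 and STV-free replicates 1, 2 and 3. Its ratios between libraries differed from those of the FPKM columns by at most 0.116%. A whole number of reads gave 99.4% to 100% of the values from 1 to 120, where it gives 85.0% to 100% of all whole numbers in that range, so in the libraries where every number can be reached the check says little. Reads were recovered by dividing by this value and rounding, and their totals per library were 13330206 to 17549408. FPKM per normalized count agreed within 2% in all 6 libraries for 91.6% of the 7797 genes above 200 normalized counts.

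Because the columns are normalized and rounded, the count model chosen beforehand for raw counts was not used, and the test fixed for normalized values took its place. Genes with a normalized count of at least 10 in at least 3 libraries were kept, 18670 of 30389, and log2(normalized count + 1) was fitted by group alone in limma 3.58.1 in R 4.3.3 with a variance trend and robust empirical Bayes. Fold changes are on this log2 scale with a pseudocount of 1, which understates the change of low genes. P-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested, and the call threshold is 0.05. The deposited scaling was kept. Rbcs-3B, at 0 in 2 libraries and at 627700 or more in the others, was left out of tests and scaling.

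Gene lists, their tests and the rule for the genes to name were chosen before the data were examined. The 26 lists were given as tomato locus identifiers and as patterns on names and descriptions. None of the 164 identifiers could be matched to the NCBI gene numbers of the table, so membership comes from the patterns alone, on the descriptions of 2370 genes and on symbols. The salicylic acid list thus lacks EDS1, PAD4 and NPR1, and the wound-induced defence list lacks threonine deaminase 2, leucine aminopeptidase A and arginase 2. Of the gene numbers, 27217 were found in the RefSeq gene table of assembly SLM_r2.1, which gave 599 further symbols to the 2333 in the deposited table. Lists therefore hold described or named genes alone, and the patterns also caught genes outside the families: the receptor-like proteins Ve1 and Ve2 among resistance-type NLR proteins, superoxide dismutases and catalases among glutathione S-transferases and peroxidases, nitrate and nitrite reductase among transporters, STH-2 proteins and SlCRF1 among pathogenesis-related proteins, and auxin efflux genes among auxin response. Lists with at least 4 tested members, 22 in all, were tested with camera (preset correlation 0.01), with camera under an estimated correlation and with fry, and each median was placed among 10000 random lists of the same size matched on expression. The named genes were to be the 10 largest rises and falls past the test, the 2 members with the smallest unadjusted p in each list with none past it, and, with fewer than 5 called genes in a direction, the 5 with the smallest unadjusted p.

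The replicate numbers were checked for pairing before the fits were compared. Deviations from the group means, correlated across genes between STV-infected and STV-free libraries, gave 0.322, 0.720 and 0.299 for replicates 1, 2 and 3, all over 0.1, while pairs with different numbers gave -0.448 to 0.109. The SE of such a correlation comes from resampling genes, which are not independent. Deviations sum to 0 within a group, so the correlation of replicate 2 bears on the others, which are not separate checks. STV-infected replicate 1 correlated more with STV-free replicate 3 (Pearson r = 0.961) than with STV-free replicate 1 (0.945), though 0.945 was the highest r of STV-free replicate 1. The numbers may thus pair the samples, from the data and not from a stated design, and less clearly for replicate 1. A fit with the replicate number as a block is given where it changes a call or a count.

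Alternatives were scaling by relative log expression, library totals, the upper quartile or TMM (formulas applied to the normalized counts), no filter or a mean of at least 5 CPM, the replicate block, the number of digits of the sample number as a batch term, limma-voom on the recovered reads, no robust estimation, pseudocounts of 0.1 and 5, stricter thresholds, FPKM values, and leaving out each library. The digits term parts replicate 1, with sample numbers 12 and 22, from the other libraries. TMM and FPKM were added after the data were seen. The gene test was tried on simulated data with independent libraries, 10 draws with 200 changed genes each, where 5.98% of 1371 calls were false. In simulated lists of 15 independent genes moved by a log2 of 0.5, camera with the preset correlation called 20 of 20, fry 9 of 20 and camera with an estimated correlation 0 of 20. None of the 3 tests called any of 100 unchanged lists, which says nothing of lists whose genes are correlated. In 10 further draws of lists with a correlation of 0.1 between members, camera with the preset correlation called 195 of 200 moved and 63 of 1000 unchanged lists and put 15.9% of the unchanged ones at an unadjusted p under 0.05. Fry called 28 and 2, and camera with an estimated correlation 0 and 0. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.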

Results

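Messenger RNA of leaves from 1-month-old tomato plants, cultivar M82, was sequenced in 3 plants carrying southern tomato virus (STV) and 3 plants free of it. STV is a persistent double-stranded RNA virus that passes through seed and gives no visible symptoms, and the study asked how the leaf transcriptome of infected plants differs from that of virus-free plants. Each plant gave 1 library, named here by its group and replicate number. The reads assigned to genes, recovered from the deposited normalized counts, numbered 16716380, 15819494 and 17549408 in STV-infected replicates 1, 2 and 3, and 16685703, 15243811 and 13330206 in STV-free replicates 1, 2 and 3. Between 21675 and 22256 of the 30389 listed genes had a value above 0 in a library, and 18670 genes were tested. The table held 0 virus features, so the infection status rests on the labels and STV RNA was not analysed here.

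Libraries of replicates 2 and 3 resembled each other by replicate number more than by infection, and those of replicate 1 less clearly so. Across the tested genes, STV-infected replicate 2 correlated best with STV-free replicate 2 (Pearson r = 0.978, Spearman rho = 0.983), and STV-infected replicate 3 with STV-free replicate 3 (r = 0.977, rho = 0.982). Within the STV-infected group r lay between 0.937 and 0.952, and within the STV-free group between 0.920 and 0.937. STV-infected replicate 1 was closest to STV-free replicate 3 (r = 0.961), and its r with STV-free replicate 1 was 0.945. STV-free replicate 1 was in turn closest to STV-infected replicate 1, and its next highest r was 0.938, with STV-infected replicate 3. These values are across genes, which are not independent replicates. Component 1 of a principal component analysis held 41.7% of the variance and set both replicate 2 libraries, at 56.6 and 64.1, apart from the other 4, which lay between -43.3 and -17.4. Component 2 held 28.5% and ran from STV-free replicate 1 at 65.8 to STV-free replicate 3 at -49.1.

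**Figure D1:**
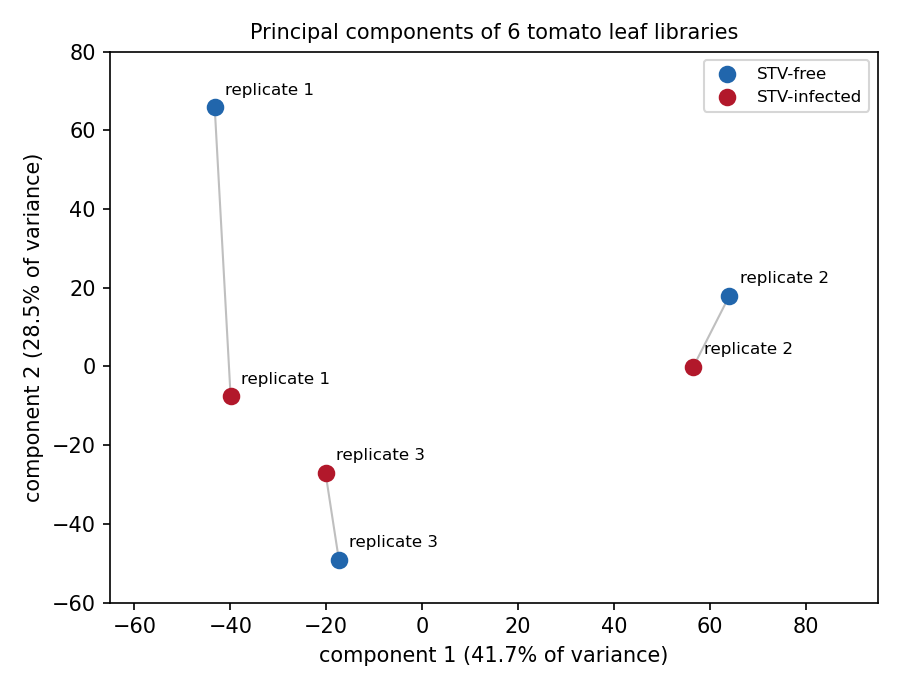
Scores of the 6 libraries on components 1 and 2 of log2(normalized count + 1) over 18670 genes, in arbitrary units, with grey lines joining libraries of the same replicate number. Both replicate 2 libraries lie to the right, at 56.6 and 64.1 on component 1, and the infected and virus-free libraries do not separate.

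Between infected and virus-free leaf no single gene passed the test over all genes. Among the named genes with the smallest p-values, most had lower normalized counts in infected leaf: ACO1, which encodes the enzyme of the last step of ethylene synthesis, the zinc finger gene ZF2, the transcription factor genes NAC1, EREB, WRKY6 and a WRKY40-like gene, and the chaperone gene hsc70.3. The higher values included TCP13, a TCP transcription factor gene of leaf growth, and a gene for an inhibitor of invertase or pectin methylesterase. Limma called 0 of 18670 genes higher and 0 lower at a Benjamini-Hochberg adjusted p under 0.05, with a smallest adjusted p of 1. At an unadjusted p under 0.05 there were 107 genes, 21 higher and 86 lower in infected leaf, where 934 are expected by chance if the libraries are independent. Without STV-infected replicate 3 limma again called 0 genes and put 184 at an unadjusted p under 0.05, and without STV-free replicate 3 it called 0 and put 536 there. Limma-voom on the recovered reads also called 0, with 107 genes at an unadjusted p under 0.05. With the replicate number as a block, limma called 0 genes and put 439 at an unadjusted p under 0.05, 172 higher and 267 lower.

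The size of the differences was small beside the spread between plants. The median absolute log2 fold change was 0.15, its 90th percentile 0.47, and 276 genes reached an absolute log2 fold change of 1. The median standard error was 0.30 and the median 95% interval reached 0.70 to either side on the log2 scale, a 1.62-fold change. With the replicate block these were 0.21, 0.51 and 1.42-fold. The values of the 2 groups did not overlap in 225 genes that were higher and 308 that were lower in infected leaf, 2.85% of the genes tested. A share of 10% is expected by chance if the 6 libraries are exchangeable, which the likeness by replicate number puts in doubt. On simulated data built from these libraries, with 18670 genes in the step, the test recovered 10.8% of genes changed 2-fold. It recovered 68.6% of those changed 4-fold and 87.2% of those changed 8-fold. The simulated libraries were independent of each other, so these shares need not hold where libraries are alike by replicate number.

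The 5 genes with the smallest unadjusted p that were lower in infected leaf, none past the test, included ACO1 and ZF2. ACO1 had 172 ± 60.5 normalized counts (SD, n = 3) in infected and 548 ± 197 (n = 3) in virus-free leaf, a log2 fold change of -1.65 (SE 0.36). ZF2 had 144 ± 19 against 285 ± 65 (SD, n = 3 each), a log2 fold change of -0.97 (SE 0.23). The other 3 have neither a name nor a described product: LOC101253257 (log2 fold change -1.22, SE 0.24), LOC104645854 (-0.99, SE 0.20) and 1 more. None of the 5 on the higher side has a name or a described product. LOC101264228 had 66, 16 and 32 normalized counts in infected and 4, 1 and 1 in virus-free leaf, and its log2(count + 1) difference of 3.63 (SE 0.70) rests on values near the lower limit and was 1.28 on FPKM values. LOC101249032 had 27.7 ± 5.5 against 7.3 ± 2.1 (SD, n = 3 each), a log2 fold change of 1.8 (SE 0.44), and 0.95 on FPKM values. On FPKM values the same pseudocount of 1 weighs more, so the change of low genes is understated further there.

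Further genes with a name or described product and small p-values were picked after their values were seen. EREB, an ethylene responsive element binding protein gene, had a log2 fold change of -2.22 (SE 0.60, and -1.45 on FPKM values) at only 14 ± 10 against 56.3 ± 2.5 normalized counts (SD, n = 3 each). NAC1 had -1.20 (SE 0.32), with 324 ± 40 against 790 ± 362 (SD, n = 3 each). TCP13 had 0.47 (SE 0.19), with 300.0 ± 43.5 against 215 ± 19 (SD, n = 3 each), and the invertase or pectin methylesterase inhibitor gene LOC101244503 had 0.96 (SE 0.36). For all of these limma's adjusted p was 1.

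**Figure D2:**
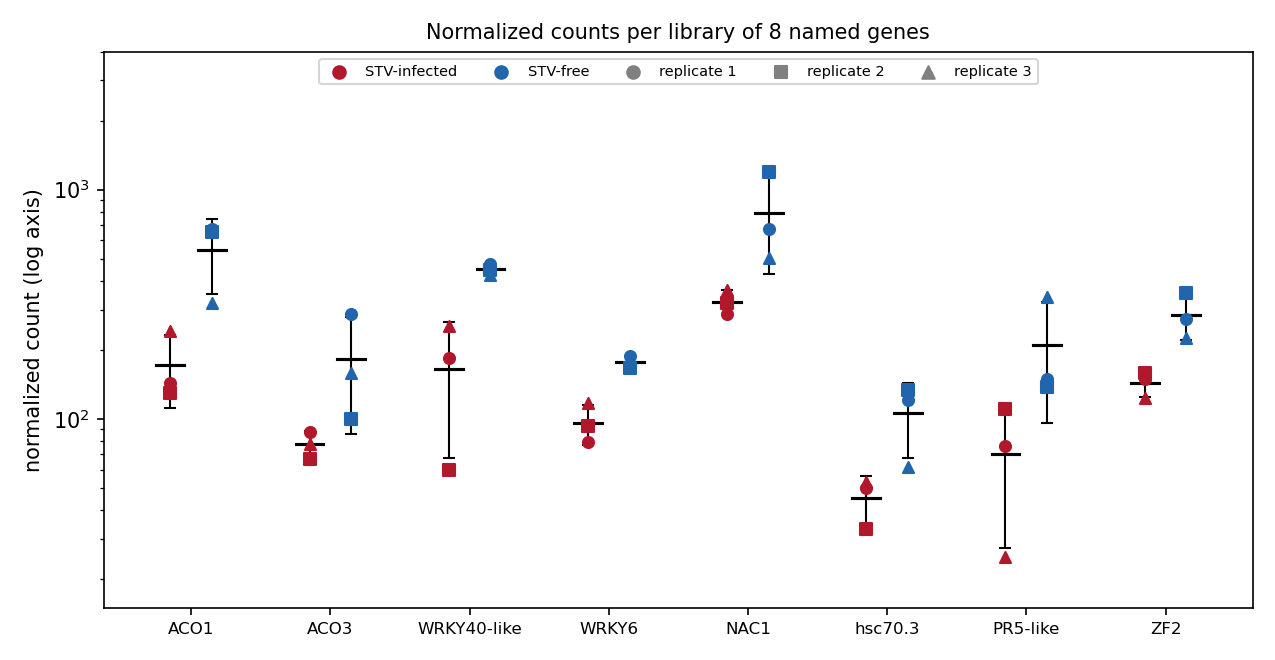
Normalized counts, on a log axis, of 8 named genes in the 3 STV-infected (red) and 3 STV-free (blue) libraries, with symbols for the replicate number, and black bars for the mean and SD of each group. In WRKY6 the infected libraries hold 79 to 117 and the virus-free ones 166 to 188 normalized counts, and in ACO1 130 to 241 against 321 to 670.

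Among the gene lists fixed before the data were examined, 4 passed camera at a preset correlation with lower values in infected leaf and 1 with higher values, and 0 passed when the correlation was estimated (adjusted p = 0.205 to 0.325 with an estimated correlation for these 5). WRKY transcription factors, regulators of defence gene expression, had a median log2 fold change of -0.45, and 17 of 18 tested members had a value below 0. Pathogenesis-related proteins had a median of -0.50 with 10 of 11 below 0, heat shock proteins -0.35 with 11 of 12 below 0, and ethylene synthesis and perception -0.20 with 10 of 14 below 0. Photosystem subunits and carbon fixation had a median of 0.19, with 13 of 13 members above 0. These 5 of the 22 lists tested passed camera with a preset correlation of 0.01 (adjusted p = 9.1e-09, 0.00054, 0.00063, 0.0098 and 0.0013 in the order given). None of the 5 passed when the correlation between genes was estimated: adjusted p = 0.205 with an estimated correlation for the WRKY, pathogenesis-related, heat shock and ethylene lists, and adjusted p = 0.325 with an estimated correlation for the photosystem list. Fry, which asks whether a list's genes move on balance to 1 side, passed 0 lists (smallest adjusted p = 0.0938, for the ethylene list). In simulated lists with a correlation of 0.1, camera with the preset correlation called 195 of 200 moved and 63 of 1000 unchanged lists. With an estimated correlation camera called 0 of the 200 moved lists. Its failure here therefore cannot decide whether a list moved. Nor can a pass at the preset correlation, which put 15.9% of those unchanged lists at an unadjusted p under 0.05. The estimated correlations were 0.106 for WRKY, 0.093 for pathogenesis-related, 0.062 for heat shock, -0.068 for ethylene and 0.135 for photosystem genes. Other splits of the libraries into 3 against 3 gave up to 8 lists past camera at the preset correlation. Among 10000 random lists matched on expression the medians of the 5 called lists lay at percentiles 0, 0, 0.03, 0.11 and 91.0. The photosystem median, at 91.0, was thus not extreme among matched lists, and this value does not back its call. Lists matched to the light-harvesting genes lay mostly above 0.08, since their median of 0.08 was at percentile 21.8. Signs above 0 may thus be common among highly expressed genes. Under scaling to library totals the photosystem median was 0.11 (camera adjusted p = 0.00493). With the replicate block camera passed 6 lists, the same 5 and glandular trichome markers (median 0.26, adjusted p = 0.0128, and adjusted p = 0.72 with an estimated correlation). Camera passed 3 lists without STV-infected replicate 2, 8 without STV-free replicate 1, and 9 without STV-infected replicate 3, without STV-free replicate 3 or with limma-voom on the recovered reads.

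In the WRKY list 0 of 18 members passed over all genes or adjusted over the list alone, and the smallest p-values belonged to WRKY6 and LOC101246812, a probable WRKY40. WRKY6 had 96.3 ± 19.2 normalized counts in infected and 176 ± 11 in virus-free leaf (SD, n = 3 each), a log2 fold change of -0.88 (SE 0.23). LOC101246812 had 166 ± 98 against 449 ± 24 (SD, n = 3 each), a log2 fold change of -1.66 (SE 0.49, -2.08 to -1.05 without 1 library), with its lowest value, 60, in STV-infected replicate 2. With the replicate block 3 members passed adjusted over the list alone, WRKY6, LOC101246812 and LOC101263542 (log2 fold change -0.72), each at limma's adjusted p = 0.0389. Among 10000 random lists matched on expression, the list median lay at percentile 0. Such lists are drawn gene by gene and lack the correlation between members, estimated at 0.106 for this list. The percentile is thus not a separate check of the camera call. By library the mean level of the list was -0.28, -0.53 and 0.02 in STV-infected replicates 1, 2 and 3 and 0.42, 0.44 and -0.08 in STV-free replicates 1, 2 and 3, as log2 differences from each gene's mean.

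In the pathogenesis-related list 0 of 11 members passed over all genes or adjusted over the list alone. The smallest p-values were those of LOC543878, a PR5-like gene, with 70.7 ± 43.2 against 209 ± 113 normalized counts (SD, n = 3 each; log2 fold change -1.67, SE 0.59, -2.11 to -1.05 without 1 library), and of TPM-1, an osmotin-like gene (log2 fold change -0.94, SE 0.46, -1.47 to -0.65 without 1 library). The list also holds SlCRF1, which its description names as the transcriptional activator PTI6 and not a secreted protein (log2 fold change -0.39). Library means were -0.57, -0.24 and -0.14 in the infected replicates 1, 2 and 3 and 0.74, 0.36 and -0.15 in the virus-free ones. Without STV-free replicate 1 the median was -0.26 and the list no longer passed camera (adjusted p = 0.0508), and the median was -0.17 without STV-free replicate 2 and -0.87 without STV-free replicate 3.

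In the ethylene list 0 of 14 members passed over all genes, and 1, ACO1, fell when adjusted over the list alone (limma, adjusted p = 0.031; lower in 3 of 3 infected libraries than in each virus-free one). With the replicate block 2 members, ACO1 and ACO3, passed adjusted over the list alone (adjusted p = 0.0418 for both). ACO1 did not pass without STV-infected replicate 1 (0.141), STV-infected replicate 2 (0.128), STV-free replicate 1 (0.148) or STV-free replicate 2 (0.0541), nor with the digits of the sample number as a batch (0.0553). ACO3, another oxidase of that step, had 77.7 ± 10.5 against 182 ± 96 normalized counts (SD, n = 3 each; log2 fold change -1.09, SE 0.38, -1.46 to -0.70 without 1 library). LE-ACS1B, of the same pathway, lay on the other side, at a log2 fold change of 0.84 (SE 0.77). Library means were -0.13, -0.18 and -0.03 in the infected replicates 1, 2 and 3 and -0.01, 0.27 and 0.08 in the virus-free ones. The list did not pass camera without STV-infected replicate 2 (adjusted p = 0.0707), STV-free replicate 2 (median -0.13, adjusted p = 0.156) or STV-free replicate 3 (median -0.10, adjusted p = 0.0703), nor without a filter on low genes (adjusted p = 0.109).

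In the heat shock list 0 of 12 members passed over all genes or adjusted over the list alone. The chaperone genes hsc70.3 and hsc70 had the smallest p-values, with log2 fold changes of -1.16 (SE 0.38) and -1.08 (SE 0.44, -1.39 to -0.63 without 1 library), and hsc70 stood at 798 to 2278 normalized counts in infected and 2088 to 4123 in virus-free leaf. Library means were 0.28, -0.78 and -0.22 in the infected replicates 1, 2 and 3 and 0.20, 0.20 and 0.31 in the virus-free ones, and without STV-infected replicate 2 the list median was -0.11 (camera adjusted p = 0.0707). The median was -0.81 without STV-infected replicate 1, and -0.14 with a filter at a mean of at least 5 CPM, where the list did not pass (adjusted p = 0.166). In the photosystem list 0 of 13 members passed over all genes or adjusted over the list alone. Its smallest p-values were those of LOC543974, a Rubisco small chain 2A gene (357350 ± 20444 against 283430 ± 51618 normalized counts, SD, n = 3 each; log2 fold change 0.35, SE 0.19, 0.22 to 0.48 without 1 library), and SLTAB2, a photosystem I-related gene (0.37, SE 0.25, 0.23 to 0.57 without 1 library). Library means of the photosystem list were 0.16, 0.12 and 0.00 in the infected replicates and 0.02, -0.25 and -0.06 in the virus-free ones. Small chain genes are near-identical copies that can share reads, so single members are uncertain. The photosystem list lost its call without STV-infected replicate 2 (adjusted p = 0.0707) or STV-free replicate 2 (adjusted p = 0.156).

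The other 17 tested lists did not pass camera (adjusted p from 0.0696 to 0.822), and in each 0 members passed over all genes and 0 adjusted over the list alone. These lists were unstable when 1 library was left out: 10 of the 17 then passed camera in at least 1 refit, and the median of 11 changed sign. Each is given with its median log2 fold change and the values of the 2 members with the smallest unadjusted p, none past the test, and parentheses hold the range of a value without 1 library. Percentiles among random lists were as low in some of them: 0 for glutathione S-transferases and peroxidases, 0.03 for jasmonate, 0.42 for ethylene-responsive factors and 0.45 for phosphate and nitrogen transport. Scaling to library totals moved the median of all genes from 0.01 to -0.07, and with it these small values. RNA silencing genes, the antiviral machinery of plants, had a median of -0.12 (-0.17 to 0.02) over 17 genes, with DCL4 at -0.23 (SE 0.18, -0.28 to -0.15) and AGO2A at -0.25 (SE 0.25, -0.43 to -0.03), and a median of -0.07 on FPKM values. Genes of salicylic acid and phenylpropanoid entry had -0.03 (-0.31 to 0.25) over 5 genes, with SAMT at 0.45 (0.13 to 0.72) and PAL5 at -0.16 (-0.57 to 0.25). EDS1, PAD4 and NPR1 were not among these genes. Jasmonate synthesis and JAZ repressors had -0.24 (-0.67 to -0.02) over 15 genes, with loxF at -1.08 (SE 0.47, -1.48 to -0.66) and aos at -1.72 (SE 0.78, -2.36 to -1.0), and passed camera without STV-infected replicate 3 (-0.19, adjusted p = 0.0106) and STV-free replicate 3 (-0.67, 0.0239), at a mean of at least 5 CPM (-0.32, 0.016) and with limma-voom (-0.30, 0.0388). Wound-induced defence had 0.03 (-0.40 to 0.33) over 12 genes, with the proteinase inhibitor gene ER1 at -1.12 (-1.75 to -0.44) and the polyphenol oxidase gene LOC101259064 at 1.20 (0.51 to 1.81); this median turned to -0.27 at a mean of at least 5 CPM and to -0.03 under scaling to library totals. Ethylene-responsive factors had -0.13 (-0.33 to -0.02) over 16 genes, with ERF5 at -0.69 (-1.05 to -0.40) and ERF-B13 at -0.86 (-1.25 to -0.47), and passed without STV-infected replicate 1 (-0.26, adjusted p = 0.00364), at a mean of at least 5 CPM (-0.27, 0.00317) and with limma-voom (-0.16, 0.0388). Gibberellin metabolism and perception had -0.13 (-0.59 to -0.01) over 6 genes, with the receptor gene GID1 at -1.0 (-1.32 to -0.47) and GA2ox3 at -0.92 (-1.38 to -0.16), and a median of -0.53 without a filter (adjusted p = 0.0633). Auxin response genes had 0.00 (-0.10 to 0.09) over 34 genes, negative under the 4 other scalings, with LOC543684 at -1.44 (-1.77 to -0.87) and LOC543701 at -0.87 (-1.35 to -0.47), and passed without STV-free replicate 1 (-0.10, adjusted p = 0.0363). Light-harvesting proteins had 0.08 (-0.27 to 0.42) over 17 genes (-0.01 under scaling to library totals), with CAB12 at 0.21 (0.03 to 0.39) and CAB9 at 0.16 (0.00 to 0.34). They passed with opposite directions, at -0.27 without STV-infected replicate 1 (adjusted p = 0.0113) and at 0.33 and 0.42 without STV-infected replicate 3 and STV-free replicate 1 (0.000825 and 6.7e-05).

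Cytosolic ribosomal proteins had a median of 0.11 (-0.13 to 0.36) over 12 genes, with LOC101250808 at 0.28 (0.12 to 0.55) and LOC101246068 at 0.23 (-0.0030 to 0.46), and plastid-type ribosomal proteins 0.13 (0.05 to 0.31) over 6 genes, with LOC101252938 at 0.28 (0.11 to 0.48) and LOC101244639 at 0.18 (0.05 to 0.34). Both passed camera without STV-free replicate 3 (0.28 and 0.31, adjusted p = 0.0452 each), and the cytosolic ones without STV-infected replicate 2 (0.36, 0.0041). Cell wall loosening genes had 0.09 (0.02 to 0.27) over 17 genes, with XTH6 at -0.77 (-1.19 to -0.29) and XTH9 at 0.70 (0.28 to 1.31), and a median of 0.19 at a mean of at least 5 CPM. Resistance-type NLR proteins had -0.04 (-0.25 to 0.41) over 7 genes, with Bs4 at 0.49 (0.13 to 0.81) and Mi-1E at -0.48 (-0.95 to -0.23). Glutathione S-transferases and peroxidases had -0.13 (-0.29 to 0.06) over 27 genes, with cevi16 at -1.18 (SE 0.43, -1.49 to -0.75) and TMP1 at 0.44 (0.31 to 0.65), and passed without STV-infected replicate 3 (-0.11, adjusted p = 0.0392) and STV-free replicate 3 (-0.29, 0.0239), and with limma-voom (-0.13, 0.0388). Phosphate and nitrogen transport had -0.17 (-0.25 to 0.07) over 11 genes, with LeAMT1;1 at -0.59 (-0.93 to -0.08) and LOC101267693 at -0.58 (-0.92 to -0.05). This median was 0.02 on FPKM values, -0.04 with a pseudocount of 5, -0.08 at a mean of at least 5 CPM and -0.09 without a filter. Flavonoid and anthocyanin synthesis had -0.17 (-1.17 to 0.93) over 10 genes, with DMR6-1 at 0.59 (0.16 to 1.38) and LOC100191129 at -0.46 (-1.89 to 0.68). It passed at -1.17 without STV-infected replicate 3 (adjusted p = 0.0106), at -1.13 without STV-free replicate 2 (0.00992) and at 0.93 without STV-free replicate 1 (0.0020), and its median was -0.11 without a filter.

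Markers of cell types that a leaf sample can hold in varying shares were fixed as lists as well. Glandular trichome markers had a median of 0.26 (0.06 to 0.67 without 1 library) over 7 genes, all above 0, with ASH3 at 0.26 (0.06 to 0.46) and MKS2b at 0.77 (-0.37 to 1.51), and library means of 0.38, -0.28 and 0.52 in infected and -0.75, -0.47 and 0.59 in virus-free replicates 1, 2 and 3. They lay at percentile 99.0 of random lists. They passed camera without STV-free replicate 3 (0.38, adjusted p = 0.0452), without a filter (0.29, 0.0404) and with limma-voom (0.26, 0.0474). With the replicate block they passed camera as well (adjusted p = 0.0128, and adjusted p = 0.72 with an estimated correlation). Their median was 0.51 at a mean of at least 5 CPM. The list fixed for dividing cells matched histones, the cyclin-dependent kinase genes SICDKA1 and cdc2A-2, and krp3 and krp4, inhibitors of such kinases, but no cyclin. It had 0.03 (-0.12 to 0.25 without 1 library) over 13 genes (-0.05 under scaling to library totals), with LOC101248710 at 0.34 (0.28 to 0.44) and SICDKA1 at 0.24 (0.19 to 0.32), and passed without STV-free replicate 1 (0.25, adjusted p = 0.0020). The remaining 4 lists had fewer than 4 tested members and no set test: chitinases had a median of -0.58 over 3 genes, phloem and xylem markers 0.16 over 2, and the single members of the circadian clock and leaf senescence lists had -0.65 and -0.40. With the replicate block the chitinase gene CHI17 (log2 fold change 0.64, limma's adjusted p over the list alone = 0.0222) passed, and it did not in the fit by group alone (0.453). LOC101265430, described as early flowering 2-like (-0.65), is the single tested member of the circadian clock list. Its limma p of 0.0336 with the block, and 0.193 by group alone, is therefore unadjusted and is not counted as a call.

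**Figure D3:**
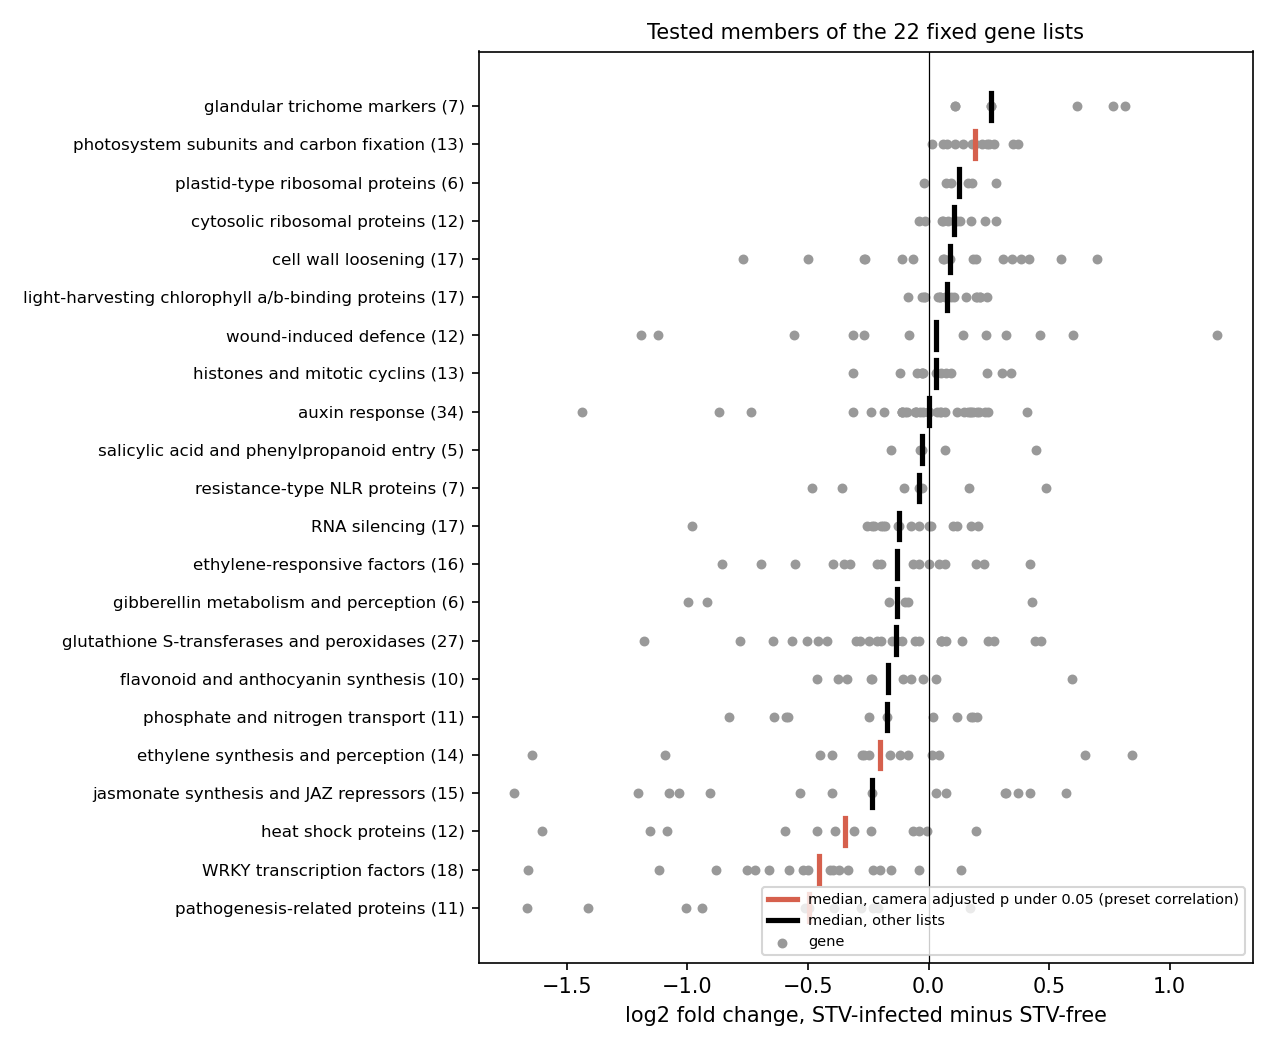
Log2 fold changes, STV-infected minus STV-free, of the tested members (grey points) of the 22 lists with at least 4 tested members, with the number of members in parentheses and a bar at each median, red where camera's adjusted p with the preset correlation was under 0.05. The medians run from -0.50 for pathogenesis-related proteins to 0.26 for glandular trichome markers, and those of light-harvesting proteins, wound-induced defence, the list for dividing cells and auxin response turn below 0 under scaling to library totals.

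The small subunit gene of Rubisco with the highest counts, Rbcs-3B, was listed at 0 in STV-infected replicates 1 and 3. It stood at 969179 normalized counts in STV-infected replicate 2 and at 763873, 627700 and 954480 in STV-free replicates 1, 2 and 3. It was the single gene at 0 in a library with more than 500 normalized counts in another, and it was left out of every test.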

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

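Scaling by TMM, FPKM values and the block with an estimated correlation or fry were chosen after the data were seen; the other alternatives were planned. The count of genes past an adjusted p of 0.05 was 0 in limma under all 21 alternatives run, including the replicate block, limma-voom and each left-out library, with 71 to 536 genes at an unadjusted p under 0.05 against 107 in the reported test (439 with the replicate block, 536 without STV-free replicate 3). DESeq2 and edgeR were not run, since the deposited values are normalized and the recovered reads are estimates that were tested with limma-voom alone, and lists by pattern alone are the lists reported.

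The count of lists past camera was 5 in the reported test, 9 with limma-voom on recovered reads, 6 with the replicate block, and 3 to 9 without 1 library. It was 0 with an estimated correlation, 0 with fry, and 0 for the replicate block with either. In simulated lists with a correlation of 0.1, camera with the preset correlation called 195 of 200 moved and 63 of 1000 unchanged lists. Fry called 28 and 2, and the estimated correlation 0 and 0. A count of 0 with an estimated correlation thus cannot decide whether a list moved, and neither can a pass at the preset correlation. The WRKY list passed camera under all 19 alternatives in which its median was refitted (-0.67 to -0.34). The ethylene list did not pass without a filter (-0.20), nor the heat shock list at a mean of at least 5 CPM (-0.14), where the genes tested differ. Without 1 library the medians ranged from -0.87 to -0.17 for pathogenesis-related proteins, -0.27 to -0.10 for ethylene, 0.15 to 0.22 for photosystem subunits and -0.81 to -0.11 for heat shock proteins. Calls were lost in 1 of these 6 refits for pathogenesis-related proteins, 3 for ethylene, 2 for the photosystem list and 1 for heat shock. Of the 17 lists not past camera, 10 passed in at least 1 alternative, each of them without 1 library or more. Adjusted over a list alone, the replicate block added 3 WRKY members, ACO3 and CHI17 to ACO1. ACO1 lost this call with the digits batch term (0.0553) and without 4 of the 6 libraries (0.0541 to 0.148).

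Of 57 named genes 39 moved by over 1.5 times or turned without 1 library, and 4 changed sign, each only without 1 library, and the cause was not tested: PAL5 (-0.57 to 0.25), LOC101246068 (-0.0030 to 0.46), MKS2b (-0.37 to 1.51) and LOC100191129 (-1.89 to 0.68). The median 95% interval reached 0.70 on the log2 scale, and 0.51 with the replicate block.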

Other observations

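Only the test on light-signalling genes was set before its result was seen; the other tests in this part were chosen afterwards.

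Single genes differed by replicate number across both groups. In a limma fit with group and number, 346 of 18670 genes differed between numbers at an adjusted p under 0.05. Replicate 1 libraries held 160 genes higher and 100 lower than the others, replicate 2 libraries 105 and 181, and replicate 3 libraries 6 and 12. LNK1, a gene tied to the circadian clock, had 7064 and 5744 normalized counts in the infected and virus-free replicate 1 and 205 to 710 elsewhere (log2 difference 4.05, SE 0.32, adjusted p = 0.014). SP5G, a photoperiod-regulated flowering repressor, was at 362 and 249 against 34 to 69 (2.77, SE 0.24, adjusted p = 0.0158). Among light-harvesting genes 6 of 17 were higher in replicate 1 and the list median was 1.07 (camera adjusted p = 8.6e-11, adjusted p = 0.629 with an estimated correlation), and in replicate 3 it was -0.72 (1.1e-08, and adjusted p = 0.974 with an estimated correlation). The aquaporin gene PIP1-7, adenylyl-sulfate reductase (LOC544267) and the early light-inducible gene ELIP were higher in replicate 1 as well, as single genes (log2 differences 1.93, 1.78 and 1.69).

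Replicate 2 libraries held less TomloxC, the lipoxygenase of leaf volatile synthesis (log2 difference -2.55, SE 0.16, adjusted p = 0.0145), and less sesquiterpene synthase SSTLE1 (-2.56, SE 0.37, adjusted p = 0.0431). They held more nicotianamine synthase CHLN, needed for iron transport (2.64, SE 0.21, adjusted p = 0.0222). The flavonoid and anthocyanin list had a median of -2.45 in replicate 2 libraries against the others (camera adjusted p = 0.0026, adjusted p = 0.941 with an estimated correlation). Its library means were -0.44, -1.40 and 1.66 in the infected replicates 1, 2 and 3 and 2.12, -1.63 and -0.31 in the virus-free ones, so replicates 1 and 3 do not agree between the groups. Within it DFR stood at 1301 normalized counts in STV-infected replicate 3 and 1115 in STV-free replicate 1, against 69 to 128 in the other 4 libraries. AnthOMT had 1630 and 1647 in the same libraries, against 61 to 120.

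Fewer small p-values than chance appeared between infected and virus-free leaf, 107 where 934 are expected. Variation shared by libraries of the same number may account for part of this: with the replicate block the count was 439, and the 6 splits of the libraries that keep 2 pairs whole gave 797 to 2759, against 27 to 462 in the 4 splits, the real one included, that part all 3 pairs. All 10 splits gave 0 genes past an adjusted p of 0.05, so the gap between the splits lies in unadjusted counts. The design allows 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 genes past an adjusted p of 0.05 (highest other 0, as many in 10 of 10 splits), 107 at an unadjusted p under 0.05 (highest other 2759, as many in 9 of 10), and 5 lists past camera (highest other 8, as many in 5 of 10). Among the 3 other splits that part all pairs, lists past camera numbered 0 to 8 and the blocked unadjusted count reached 2102. With the block the lists past camera reached 8 in these splits, against 6 in the real one. These list counts are at the preset correlation, and with an estimated correlation 0 lists passed in each of the 10 splits without the block.

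Libraries with the same replicate number deviated together, with correlations that are not independent, since deviations within a group sum to 0. For replicates 2 and 3 a difference in depth is argued against: the correlations were 0.720 (SE 0.0062 over genes) and 0.299 (SE 0.014), while the depths departed from their group means to opposite sides (log2 -0.08 and 0.07 in the infected, 0.02 and -0.17 in the virus-free libraries). For replicate 1 the depths departed to the same side, by log2 0.003 in the infected and 0.15 in the virus-free library. Thinning to equal depth moved no correlation by more than 0.0142. It left that of replicate 1 at 0.317, against 0.322 (SE 0.013 over genes) before. In genes over a mean of 1000 normalized counts the replicate 1 correlation was 0.427. These values argue against a difference in depth for replicate 1 as well. A few strongly variable genes are argued against, with a lowest same-number correlation of 0.302 on ranks. A hypothesis from LNK1 and the light-harvesting genes is that replicate 1 plants were sampled at another time of day or under other light. Of the 5 light-signalling genes picked for it, 4 were tested. Their median absolute log2 difference, 0.43, lay at percentile 79.9 of random lists, short of the 95th set beforehand. Time of day and a shared growth, harvest or library batch thus stay open, and the labels name none of these. The sample numbers are 12 and 22 in replicate 1 and 412, 422, 432 and 433 in the others, without a stated meaning.

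Rbcs-3B was listed at 0 in STV-infected replicates 1 and 3. Infection shutting the gene off is argued against by 969179 normalized counts in STV-infected replicate 2, above each virus-free library. A limit on the reads counted per locus is a candidate explanation: where measured, the gene held 2.69 to 2.83 times the reads of small chain 2A and at most 884287 reads, and at the lowest of these ratios it would reach 1061167 and 1129711 reads in the libraries at 0, past a limit of 1000000. Whether such a limit was set is not given in the sources used here.

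A shift in isoform use with infection was tested through FPKM per normalized count, which moves with the length of the transcripts counted. Of 658 genes where this ratio varied, limma called 0 (smallest adjusted p = 0.999, 1 at an unadjusted p under 0.05). In 367 the 95% interval of the ratio lay within a log2 change of 0.1, and the other genes stay undecided. A shift between isoforms of like length would leave the ratio unchanged, so none of the genes was tested for that.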
